A study of Homo sapiens with 38 samples.

How the data were processed

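The series holds 38 ChIP-seq libraries of HepG2 cells that carried a non-targeting hairpin (control cells), a hairpin against BRG1 or a hairpin against BRM. Per the labels, cells were selected with puromycin at 2 ug/mL after transduction with polybrene at 8 ug/mL, harvested on day 7 and fixed with 0.3% formaldehyde for 30 minutes. The 6 peak lists rest on 26 of the libraries: for each of the antibodies against BRG1 and BRM, 4 from control cells, 5 after BRG1 knockdown and 4 after BRM knockdown. The 4 H3K27ac and 8 input libraries were not analysed here. Of the input libraries 4 came from control and 4 from BRG1 knockdown cells, and 0 from BRM knockdown cells. Which input was used in calling each list is not stated.

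Per the submitters' processing notes, reads were processed against hg19 with Bowtie2, SAMtools, deepTools, MACS2 and bedtools, for which no versions are stated. Libraries of the later part of the series also name Picard: 2 of 4 control, 3 of 5 BRG1 knockdown and 4 of 4 BRM knockdown libraries of each antibody. The deposited lists hold filtered narrow peaks, 1 list per antibody and hairpin, and whether peaks were called on pooled reads is not stated. The unit of the deposited columns is other than a signal: positions, widths and distances in bp, and text for the genomic class, the name of a TSS and the chromatin state at each peak. Widths equal the end minus the start plus 1. The cell type of the chromatin state segmentation is not stated. No list holds a height, fold enrichment, score or q-value, so the depth per sample is unknown, peak width took the place of fold enrichment wherever peaks were ranked or stratified, and a planned threshold on -log10 q could not be applied.

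The deposited TSS name of a peak is that of the next TSS at a higher coordinate. Of 101466 peaks, 85.4% shared an implied TSS position with another peak when distances were read in that direction, against 0.126% in the other. From these implied positions 33874 TSS positions were recovered, and each peak was assigned to the nearest recovered TSS on either side. A recovered TSS was closer than the deposited one for 38.0% of peaks. Of peaks in the authors' promoter class, 32.1% have a deposited distance above 1000 bp, and 93.3% lie within 1000 bp of a recovered TSS, against 0.111% of other peaks. Of 20258 symbols in the lists, 15419 matched the reference table of gene names, and 12431 protein-coding genes had a recovered TSS. Genes without a recovered TSS could not be assigned a peak. Promoter peaks are those with their midpoint within 1000 bp of a recovered TSS.

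A peak of the first list was counted as kept or shared when a peak of the second overlapped it by at least 1 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The second list was shifted along the chromosomes 100 times to give the overlap of unrelated positions. Shifted peaks do not stay at promoters or enhancers, so this is not the overlap to be had between any lists of such sites. Promoter against distal and shared against unshared peaks were compared by Mantel-Haenszel odds ratios within 10 strata of control peak width. Their intervals come from 1000 resamples of whole chromosomes, and their chi-square p-values, two-sided, were adjusted over 6 tests by Benjamini and Hochberg. The smallest p written is 1.0e-300. Ratios of odds ratios, added after the data were seen, used the same chromosome resamples for both. Peaks of a list are not replicates. The chi-square test counts each peak as a unit, so its p-values do not measure how a difference varies between libraries.

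Before the data were examined, the comparisons, tests, 14 gene lists, main alternative settings and the rule for named genes were fixed. The gene lists are SWI/SNF subunits, hepatocyte secreted proteins, lipoproteins and lipid transport, cholesterol and fatty acid synthesis, bile acid and xenobiotic metabolism, liver transcription factors, AP-1 and immediate early genes, TGF-beta, mesenchymal and matrix genes, cell cycle genes, glycolysis and hypoxia genes, ribosomal protein genes, interferon and inflammation genes, markers of other liver cell types, and neuronal and muscle genes. A gene kept a factor when at least 1 of its control peaks was kept. The share of kept genes in a list was placed among 10000 random lists matched on the width decile of the gene's widest peak and its number of peaks, with limits that leave 2.5% of the random lists outside on either side. Occupancy of the lists in control cells was compared with all protein-coding genes of the reference by Fisher's exact test, two-sided, adjusted over 28 tests. Because a gene without a recovered TSS cannot be assigned a peak, the test was repeated among genes with a recovered TSS after the data were seen, with 0.5 added to each count of an odds ratio where a count was 0. The comparison of the same genes after both knockdowns, and that of strong enhancer and active promoter states among sites kept by a single knockdown, were added after the data were seen.

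The rule for named genes takes, for each comparison, the 5 widest control peaks that were kept, the 5 widest not called and the 5 widest knockdown peaks without a control peak, 1 peak per gene, and from each gene list the gene with the widest control peak among those that kept a peak and among those that kept none. SMARCA4 and SMARCA2 are named in every list, and for the overlap of BRM with BRG1 the 5 widest shared and the 5 widest unshared BRM peaks. Not every gene that the rule takes is named in the text. ALB, AFP and the peaks left after BRM knockdown were chosen after their values were seen, as were genes named as members kept by a single knockdown.

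Alternative settings fixed at the same time were an overlap of 50% of the shorter peak, a gap of up to 500 bp, lists of equal length, leaving out chromosomes 2, 14, 16, 17 and 20, which HepG2 cells carry in extra copies, promoters within 3000 bp, genes from peaks within 10000 bp only, and no strata. Added after the data were seen were 200 bp windows around the midpoints, the widest 50% of each list, the authors' promoter class, the authors' TSS names, occupancy among genes with a recovered TSS and all settings for the ratios of odds ratios and for sites that gained BRM. The methods were tested on simulated data. Overlap calls differed from brute force in 0 of 200 random lists. With a true odds ratio of 1 the mean estimate was 1.00 where the unstratified estimate was 2.34, and 93.5% of intervals held the true value. With a true odds ratio of 2 it was 2.00 against 4.05, and 95.5% did. In both simulations the class and the kept share depended on width through its decile alone, which the strata remove by construction. Differences within a decile or through peak height were not simulated. The recovery of TSS positions gave 0 false positions and the right nearest distance for 93.4% of 10000 peaks. The simulated distances all ran exactly to the next TSS at a higher coordinate, so 0 false positions followed from the setting. Random lists of 30 simulated genes fell outside the limits in 2% of cases, and such lists with 30 points added to the kept share were found in 94%. Many of the lists analysed held fewer genes with a control peak, down to 1, and detection was not simulated for those. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.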

Results

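Chromatin immunoprecipitation with sequencing (ChIP-seq) mapped BRG1 (SMARCA4) and BRM (SMARCA2) in HepG2 cells, an established human hepatoma line. BRG1 and BRM are the alternative ATPases of the SWI/SNF chromatin remodelling complexes, and a complex holds either of them. Cells carried a non-targeting short hairpin RNA (control cells), a hairpin against BRG1 or a hairpin against BRM, and were harvested on day 7. The series asks how loss of BRG1 changes the occupancy of SWI/SNF complexes. For each antibody, 4 libraries came from control cells, 5 from BRG1 knockdown cells and 4 from BRM knockdown cells. The authors deposited a single peak list for all libraries of each of these 6 groups, so there was no replicate error for any value below. The lists hold peak positions in hg19 without heights or read counts, so the depth behind them is unknown. Intervals are 95% exact binomial intervals, which cover counting error only, unless stated otherwise. A control peak is called kept when a peak of the same antibody after knockdown overlapped it by at least 1 bp. A peak that was not called may lie below the threshold of the calling, so its absence from a list does not show that binding was lost.

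In control cells the BRG1 list held 44174 peaks and the BRM list 16587. Knockdown of BRG1 left 18997 BRG1 peaks and 11650 BRM peaks, and knockdown of BRM left 9968 BRG1 peaks and 90 BRM peaks. BRG1 peaks in control cells covered 26657 kb with a median width of 411 bp, against medians of 111 to 145 bp in the 5 other lists. The narrowest peak of the control BRG1 list was 214 bp, and those of the other lists were 69 to 76 bp. Whether the control BRG1 list was called or merged with another setting is not stated, and its number of peaks and every share kept, shared or new relative to it depend on that. The control BRG1 list was also the least bound to promoters, with 47.0% of its peaks within 1000 bp of a transcription start site (TSS), against 66.7% to 83.5% in the others. Strong enhancer states held 27.0% of control BRG1 peaks and 8.28% of control BRM peaks, while active promoter states held 33.3% and 71.9%.

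**Figure D1:**
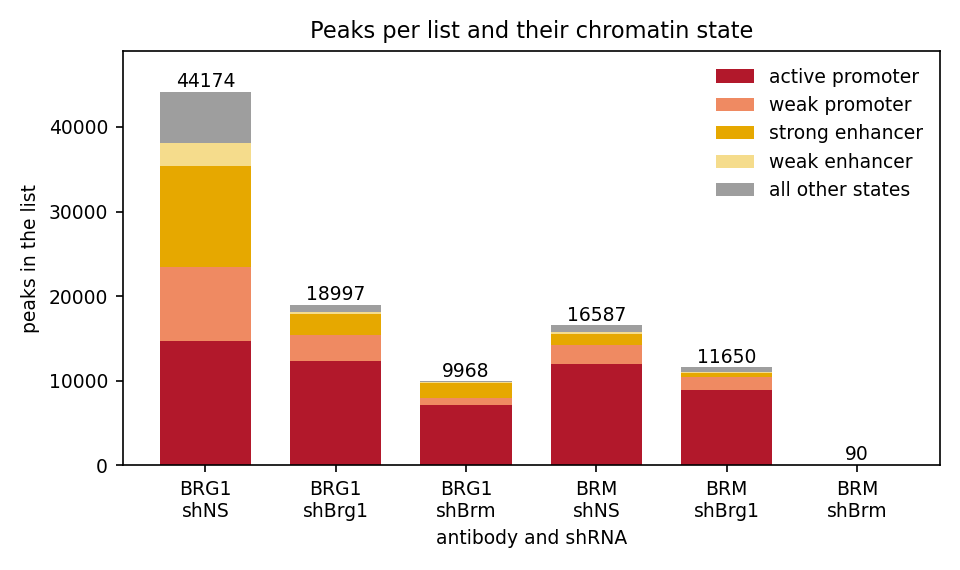
Bars give the number of peaks in each of the 6 deposited lists, by antibody and hairpin, on a linear axis that starts at 0, with colours for the chromatin state. The BRG1 list of control cells is the longest with 44174 peaks, and the BRM list after BRM knockdown holds 90.

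Whether each hairpin reduced occupancy of its own target was read from the same antibody. BRM knockdown left 85 of 16587 control BRM peaks (0.512%; 0.410 to 0.633), and counting peaks within 500 bp of each other as overlapping raised this to 0.826%. The widest of the 90 remaining BRM peaks lay at ZFP36L2 (chromosome 2, 43451474 to 43452851), an RNA-binding protein of mRNA decay. The next were at EEF1A1, a translation elongation factor, SP5, a transcription factor, IRF2BP2, a transcriptional corepressor, and MYC. These 90 peaks and their genes were looked at after their number was seen. BRG1 knockdown left 11630 of 44174 control BRG1 peaks (26.3%; 25.9 to 26.7), against a mean of 0.623% when the knockdown list was shifted along the chromosomes. With lists of equal length the share was 52.4%.

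The genes of both ATPases carried peaks themselves. At SMARCA4, a 1950 bp BRG1 peak at the promoter (chromosome 19, 11070558 to 11072507) was accompanied by 2 smaller BRG1 peaks and by 1 BRM peak of 223 bp in control cells. Each BRG1 list after knockdown held 2 narrow peaks there, the BRM list after BRG1 knockdown held 2, and the BRM list after BRM knockdown held 0. At SMARCA2, a 2527 bp BRG1 peak spanned the TSS (chromosome 9, 2015822 to 2018348), and 3 BRG1 peaks and 2 BRM peaks were called in control cells. After BRG1 knockdown 3 BRG1 peaks of 98 to 183 bp were listed at SMARCA2 with a BRM peak of 70 bp that overlapped neither control BRM peak, and after BRM knockdown no peak of either antibody was called. Levels of the BRG1 and BRM transcripts or proteins were not analysed here.

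Nearly all BRM sites of control cells were also BRG1 sites. Of 16587 BRM peaks, 16418 overlapped a BRG1 peak (99.0%; 98.8 to 99.1), against a mean of 1.9% with shifted lists. BRG1 reached further, since 9538 of 44174 BRG1 peaks overlapped BRM (21.6%; 21.2 to 22; 0.538% shifted). The widest shared BRM peaks lay at ARHGDIA (chromosome 17, 79826054 to 79828894), AXIN2, a feedback inhibitor of Wnt signalling (chromosome 17, 63554291 to 63557123), and PTMA, prothymosin alpha (chromosome 2, 232573264 to 232576077). ZFP36L2 and OAZ1, the antizyme of ornithine decarboxylase, followed with peaks of 2681 and 2509 bp. The 169 BRM peaks outside BRG1 sites were narrow. The widest of them measured 183 bp in an intron of FASN, fatty acid synthase, and the next were at DUX4L5, EME2, BRF1 and ADAM11. The overlap depended on the width of control BRG1 peaks: with every peak replaced by a 200 bp window around its midpoint, 47.9% of BRM peaks overlapped BRG1. With lists of equal length, 50.8% of BRG1 peaks overlapped BRM.

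Gene lists fixed in advance were compared with other genes for the presence of the ATPases in control cells. Of 19976 protein-coding genes, 57.6% had a BRG1 peak and 32.8% a BRM peak assigned to them. Against all of these genes, BRG1 passed as over-represented in 9 of 14 lists and as under-represented in 3, and BRM in 6 and 1 (Fisher's exact test, two-sided, adjusted over 28 tests). A TSS is known here only through a listed peak, and 92.6% of the 12431 protein-coding genes with a TSS had BRG1, so these calls largely state whether a TSS was recovered. Among genes with a TSS only, a comparison added after the data were seen, no list passed for BRG1 (lowest exact adjusted p = 0.34), and neither enrichment nor depletion of BRG1 can be read from the lists. BRG1 was present at 26 of 27 SWI/SNF subunit genes with a TSS, 29 of 32 secreted hepatocyte protein genes, 22 of 23 lipoprotein genes, 23 of 25 cholesterol and fatty acid synthesis genes and 31 of 31 liver transcription factors. It was present at 27 of 27 immediate early genes, 34 of 35 cell cycle genes, 28 of 31 glycolysis and hypoxia genes, 45 of 47 ribosomal protein genes, 24 of 26 TGF-beta, mesenchymal and matrix genes and 24 of 24 interferon and inflammation genes. Markers of other liver cell types had BRG1 at 6 of 6, neuronal and muscle genes at 11 of 13 and bile acid and xenobiotic genes at 13 of 16, and 20, 17 and 18 further members of these lists had no TSS and could not be assigned a peak.

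BRM was present at 52.7% of protein-coding genes with a TSS, and 4 of the 14 lists passed among them. Ribosomal protein genes had BRM at 39 of 47 (odds ratio 4.40; exact adjusted p = 0.00066), immediate early genes, among them MYC and KLF6, at 22 of 27 (3.96; exact adjusted p = 0.021) and cell cycle genes at 28 of 35 (3.60; exact adjusted p = 0.011). Neuronal and muscle genes had BRM at 1 of 13 (odds ratio 0.0747; exact adjusted p = 0.011). These 4 lists had also passed against all genes. The other 3 lists that had passed against all genes did not pass among genes with a TSS: liver transcription factors, with 23 of 31 (exact adjusted p = 0.1), cholesterol and fatty acid synthesis genes, with 19 of 25 (exact adjusted p = 0.12), and SWI/SNF subunits, with 20 of 27 (exact adjusted p = 0.13). Secreted hepatocyte protein genes such as TF and AGT had BRM at 11 of 32 (odds ratio 0.470; exact adjusted p = 0.17), and lipoprotein genes at 12 of 23, glycolysis and hypoxia genes at 17 of 31, TGF-beta, mesenchymal and matrix genes at 17 of 26, interferon and inflammation genes at 12 of 24, bile acid and xenobiotic genes at 6 of 16 and other liver cell types at 4 of 6 did not pass either.

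The effect of BRG1 loss on BRM is the question in the title of the series. BRM peaks were fewer, and promoter peaks were kept more often than the rest: 8124 of 16587 control BRM peaks were kept (49.0%; 48.2 to 49.7; 0.217% with shifted lists). Peaks in active promoter states were kept in 56.0%, in weak promoter states in 38.0%, in strong enhancer states in 21.7% and in transcribed states in 17.4%. These shares have no width strata. Control BRM peaks were wider in active promoters (median 151 bp) than in weak promoters (121 bp), strong enhancers (125 bp) and transcribed states (109.5 bp). The widest kept BRM peaks were those at ARHGDIA, AXIN2, PTMA, ZFP36L2 and OAZ1. The widest control BRM peaks that were not called lay at DHRS2, a short-chain dehydrogenase (chromosome 14, 24105753 to 24107779), SLC17A9, a vesicular nucleotide transporter (chromosome 20, 61584291 to 61585616), HDAC10, a deacetylase (chromosome 22, 50689079 to 50690023), the pseudogene SMG1P3 and ADRM1, a ubiquitin receptor of the proteasome. Within deciles of control peak width, promoter peaks were kept more often than distal peaks, with an odds ratio of 1.94 (chromosomes resampled, 1.57 to 2.33), 52.6% against 33.9%, above 1 on 20 of 23 chromosomes (Mantel-Haenszel chi-square test, adjusted p = 2.5e-50). Peaks shared with BRG1 were kept in 49.4% and the 169 unshared peaks in 11.2%, an odds ratio of 3.82 (2.55 to 6.19; chi-square adjusted p = 1.6e-08) above 1 on 21 of 23 chromosomes. This ratio was 1.24 with 200 bp windows, 1.67 with lists of equal length, 6.58 with peaks within 500 bp and 7.70 without width strata. Sites called for both antibodies may be easily detected sites, and width strata do not account for peak height. The ratio therefore does not show that BRG1 at a site favours the keeping of BRM.

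**Figure D2:**
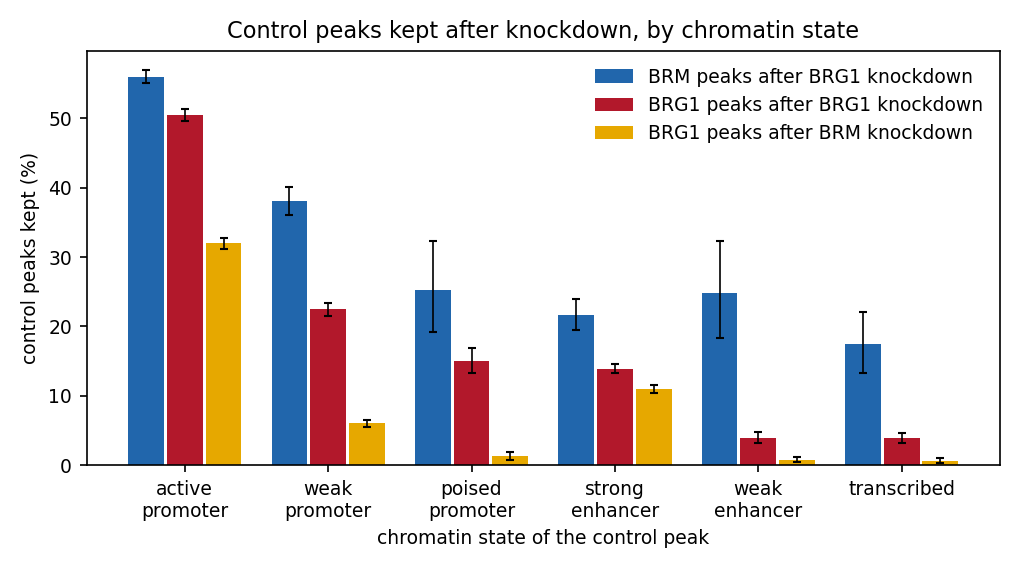
Share of control peaks kept after knockdown (percent) in 6 chromatin states, for BRM after BRG1 knockdown and for BRG1 after either knockdown, with 95% exact binomial intervals. Active promoter peaks were kept in 56.0% (BRM after BRG1 knockdown), 50.5% (BRG1 after BRG1 knockdown) and 32.0% (BRG1 after BRM knockdown). The shares are not adjusted for the width of the control peaks.

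After BRG1 knockdown, 2 of 14 gene lists kept BRM less often than matched random lists. Of 6549 protein-coding genes with a control BRM peak, 4297 kept at least 1 (65.6%). Among 23 liver transcription factor genes, 13 kept BRM (56.5%), against a median of 82.6% in random gene lists matched on peak width and number (percentile 0.205). HHEX, a homeobox factor of liver development, kept its 1177 bp peak (chromosome 10, 94451063 to 94452239), and GATA4 kept none. Of 11 secreted hepatocyte protein genes with BRM, 2 kept it (18.2%; percentile 0.455; median 54.5%). RBP4, the plasma carrier of retinol, kept BRM and the complement gene C3 did not. These percentiles moved inside the range of the random lists under some settings: to 2.79 for the transcription factors both within 500 bp and with the widest 50% of each list, and to 39.3 for the hepatocyte genes with the widest 50%, where 4 genes were left.

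The other 12 lists lay within the range of the random lists. Immediate early genes kept BRM at 21 of 22 (95.5%; percentile 96.8), with MYC among them and NR4A2 as the exception. Glycolysis and hypoxia genes kept it at 16 of 17, with VEGFA kept and SLC2A3 not. Cell cycle genes kept BRM at 14 of 28 (50%; percentile 2.80), with CCND1 kept and MCM3, a subunit of the replicative helicase, not, and passed the lower limit with the widest 50% of each list (0.7). Interferon and inflammation genes kept it at 10 of 12, with ISG15 kept and IRF2 not, and passed the upper limit with the authors' TSS names (98.8). SWI/SNF subunits kept BRM at 14 of 20, with BICRAL kept and SMARCA2 not, and cholesterol and fatty acid synthesis genes at 14 of 19, with FASN kept and LSS, lanosterol synthase, not. Ribosomal protein genes kept BRM at 27 of 39, with RPL10A among those that kept it, TGF-beta, mesenchymal and matrix genes at 12 of 17, with TGFBR2 kept and TGFB1 not, and lipoprotein genes at 6 of 12, with APOB kept and LRP1 not. Bile acid and xenobiotic genes kept BRM at 5 of 6, with POR kept and CYP1A1 not, other liver cell types at 3 of 4, with MUC1 kept and CD68 not, and TUBB3 was the 1 neuronal gene with BRM and kept it.

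The BRM list after BRG1 knockdown also held peaks that overlapped no peak of the control BRM list. They numbered 3168 of 11650 (27.2%; 26.4 to 28.0), and 2960 of them lay at control BRG1 sites (93.4%; 92.5 to 94.3; 1.45% with shifted lists). Of the 3168, 1625 lay in a BRG1 site that held a control BRM peak elsewhere, 1335 in a BRG1 site without control BRM and 208 at no BRG1 site. Active promoter states held 61.7% of them, weak promoter states 20.2% and strong enhancer states 4.89%. They were narrow, with a median of 103 bp against 157 bp for BRM peaks that overlapped a control peak. The widest were at SHANK2, a synaptic scaffold gene (chromosome 11, 70963415 to 70964004), CEP85L, a centrosomal protein gene (chromosome 6, 118972123 to 118972675), STT3B, a subunit of the oligosaccharyltransferase (chromosome 3, 31574426 to 31574972), and B3GNT9, a glycosyltransferase gene, and in a distal stretch of chromosome 3 (144517918 to 144518452), 723137 bp from the nearest recovered TSS. In control cells SHANK2 and STT3B each had 3 other BRM peaks assigned to them, and CEP85L and B3GNT9 had 0. The share of new BRM peaks was 13.2% when a gap of 500 bp was allowed. With 200 bp windows, 44.6% of such BRM windows lay at BRG1 windows.

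The reciprocal comparison asks what BRM loss does to BRG1. After BRM knockdown 6639 of 44174 control BRG1 peaks were kept (15%; 14.7 to 15.4; 0.340% with shifted lists), which is fewer than the 26.3% after knockdown of BRG1 itself. The 9968 widest peaks of the BRG1 knockdown list, as many as the list after BRM knockdown holds, kept 16.8% (16.5 to 17.2). Of either knockdown list, 96.5% of peaks lay at control BRG1 peaks, so list length and the number of kept peaks were nearly the same quantity. Whether list length or the knockdown lies behind the gap cannot be told from this. With the control list shortened to 9968 peaks, 46.4% were kept after BRM knockdown. Kept sites were mainly active promoters, where 32.0% were kept, against 11% in strong enhancers, 6.06% in weak promoters and 1.28% in poised promoters. These shares have no width strata. Control peaks were wider in active promoters (median 663 bp) than in strong enhancers (363 bp), weak promoters (400 bp) and poised promoters (353 bp). The widest kept peaks covered the cluster of 5S ribosomal RNA genes on chromosome 1, at RNA5S11 (228762457 to 228773690), RNA5S2 (228744056 to 228753643) and RNA5S15 (228773834 to 228781777), and SNX5, a sorting nexin, and SNORD12, a small nucleolar RNA, on chromosome 20. The widest BRG1 peak not called lay at GAPDH, the glycolytic enzyme (chromosome 12, 6641549 to 6647161). Next came a peak assigned to FASN (chromosome 17, 80034810 to 80039977), SNORD32A (chromosome 19, 49990760 to 49995575), the tetraspanin gene TSPAN4 and the netrin gene NTN3. Promoter peaks were kept more often than distal peaks, 23.1% against 7.91%, with an odds ratio of 1.60 (1.50 to 1.75) above 1 on 21 of 23 chromosomes (chi-square adjusted p = 5.1e-43), and 3.49 without width strata. Peaks shared with BRM were kept in 50.1% and unshared peaks in 5.36%, with an odds ratio of 4.81 (4.45 to 5.27) above 1 on all 23 chromosomes and 17.7 without width strata. The chi-square adjusted p was 1.0e-300, the smallest value written. Shared sites may again be the easily detected ones, so this odds ratio does not show that BRM at a site favours the keeping of BRG1.

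Of 11513 protein-coding genes with a control BRG1 peak, 4256 kept at least 1 after BRM knockdown (37.0%). Lipoprotein and lipid transport genes kept BRG1 less often than matched random lists, at 6 of 22 (27.3%; percentile 1.69; median 45.5%), with APOB kept and LCAT, which esterifies cholesterol in plasma, not. This call ended within 500 bp (4.13), with the authors' TSS names (6.74) and with the widest 50% of each list (14.1). The other 13 lists lay within the random range. Secreted hepatocyte protein genes kept BRG1 at 14 of 29 (48.3%; percentile 96.0), with TF, transferrin, kept and F2, prothrombin, not. Interferon and inflammation genes kept it at 13 of 24 (54.2%; percentile 97.3), with NFKBIA kept and SOCS3 not, and passed with the widest 50% of each list (98.1). Liver transcription factors kept BRG1 at 18 of 31, with FOXA2 kept and KLF15 not, and immediate early genes at 15 of 27, with KLF6 kept and KLF10 not. SWI/SNF subunits kept it at 13 of 26, with ARID1A kept and SMARCA2 not, and cell cycle genes at 14 of 34, with CCND1 kept and CCND3 not. Glycolysis and hypoxia genes kept BRG1 at 17 of 28, with ADM kept and GAPDH not, and cholesterol and fatty acid synthesis genes at 12 of 23, with FASN kept and SCD not. TGF-beta, mesenchymal and matrix genes kept it at 13 of 24, with SMAD3 kept and TGFB1 not, and ribosomal protein genes at 17 of 45, with RPL37 kept and RPS15 not. Bile acid and xenobiotic genes kept BRG1 at 6 of 13, other liver cell types at 1 of 6, which was EPCAM, and neuronal and muscle genes at 1 of 11, which was TUBB3.

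Few peaks of the BRG1 list after BRM knockdown lay outside control BRG1 peaks. Of 9968 peaks, 345 overlapped no control BRG1 peak (3.46%; 3.11 to 3.84), and 65.2% of them lay in strong enhancer states and 16.8% in active promoters. The widest were at CENPN, a centromere protein gene (chromosome 16, 81038699 to 81038979), VPS54, a vesicle tethering gene (chromosome 2, 64251297 to 64251553), the transporter gene ABCA9, MBP (43105 bp from its TSS) and EMBP1. The share was 1.81% when a gap of 500 bp was allowed, 24.8% with lists of equal length and 52.6% with 200 bp windows. All BRM knockdown libraries belong to the later part of the series, whose processing notes also name Picard, while 2 of 4 control and 3 of 5 BRG1 knockdown libraries of each antibody do. Input libraries came from control cells (4) and BRG1 knockdown cells (4), and 0 from BRM knockdown cells. Since a single list was deposited for all libraries of a group, no value within either part could be computed. Neither difference can be told apart from the knockdown of BRM.

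By TSS distance and within width deciles, the preference of kept BRG1 peaks for promoters was larger after BRG1 than after BRM knockdown, with a ratio of the odds ratios (BRM over BRG1 knockdown) of 0.616 (0.551 to 0.689). The part in active promoter states, without width strata, had the other order: active promoters held 7420 of the 11630 kept peaks after BRG1 knockdown and 4699 of the 6639 after BRM knockdown, and 65.1% and 72.0% of the 2 knockdown lists. The kept share after BRG1 knockdown, also without width strata, was 50.5% in active promoters, 22.5% in weak promoters, 15% in poised promoters and 13.9% in strong enhancers. Promoter peaks were kept in 41.1% and distal peaks in 13.2%, with an odds ratio of 2.60 (2.39 to 2.83) above 1 on 22 of 23 chromosomes (chi-square adjusted p = 7.3e-245), and 4.61 without width strata. Peaks shared with BRM were kept in 78.7% and unshared peaks in 11.9%, an odds ratio of 7.18 (6.45 to 8.00) above 1 on 23 of 23 chromosomes (chi-square adjusted p = 1.0e-300, the smallest value written) and of 27.4 without width strata. The limit that shared sites may be easily detected ones holds for this comparison as well. The 5 widest kept peaks were the same as after BRM knockdown. The widest peaks not called were those at FASN and SNORD32A named above, followed by FGL1, a fibrinogen-like protein secreted by hepatocytes (chromosome 8, 17765098 to 17768376), SLC13A3, a dicarboxylate transporter (chromosome 20, 45302747 to 45305807), and APOA2, an apolipoprotein of high-density lipoprotein (chromosome 1, 161190409 to 161193415). Of the 18997 BRG1 peaks, 664 overlapped no control BRG1 peak. The widest of these lay at HBB, beta globin (chromosome 11, 5246153 to 5247295), in the state class of heterochromatin or low signal. The next lay in the same distal stretch of chromosome 3, 723145 bp from the nearest recovered TSS, and 6527 to 9894 bp from the TSS of the pseudogenes RPS10P28 and RN7SL636P and of DNAH17, a dynein gene.

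**Figure D3:**
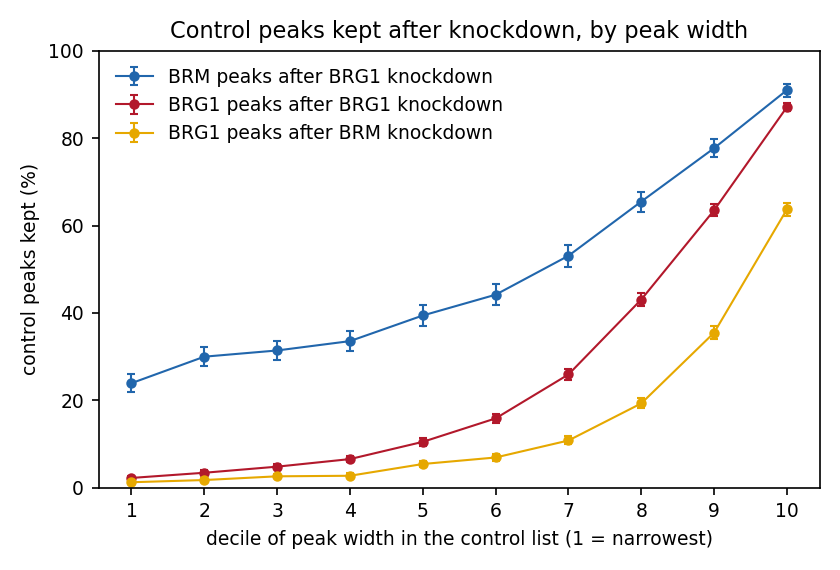
Share of control peaks kept after knockdown (percent) against the decile of control peak width, with 95% exact binomial intervals. From the narrowest to the widest decile the share rises from 23.9% to 91.0% for BRM after BRG1 knockdown, from 2.26% to 87.1% for BRG1 after BRG1 knockdown and from 1.28% to 63.7% for BRG1 after BRM knockdown.

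After BRG1 knockdown, 3 of 14 gene lists kept BRG1 less often than matched random lists. Of 11513 genes with a control BRG1 peak, 7147 kept at least 1 (62.1%), whereas secreted hepatocyte protein genes kept BRG1 at 9 of 29 (31.0%; percentile 0.005; median of the random lists 58.6%). TF kept it and AGT, angiotensinogen, did not. Lipoprotein and lipid transport genes kept BRG1 at 10 of 22 (45.5%; percentile 0.090; median 72.7%), with APOB kept and APOA2 not. Ribosomal protein genes kept it at 28 of 45 (62.2%; percentile 1.64; median 73.3%), with RPS15 kept and RPL37 not, and this call ended within 500 bp (6.25) and with the authors' TSS names (4.96). The other 11 lists lay within the random range. SWI/SNF subunits kept BRG1 at 23 of 26 (88.5%), with ARID1A kept and BCL7B not, and passed the upper limit with the authors' TSS names (97.6). Immediate early genes kept it at 23 of 27, with KLF6 kept and FOSB not, liver transcription factors at 23 of 31 (percentile 13), with FOXA2 kept and ESRRA not, and cholesterol and fatty acid synthesis genes at 19 of 23, with FASN kept and PMVK not. Cell cycle genes kept BRG1 at 24 of 34, with CCND1 kept and CCNB1 not, glycolysis and hypoxia genes at 21 of 28, with GAPDH kept and PFKFB4 not, and TGF-beta, mesenchymal and matrix genes at 17 of 24, with SMAD3 kept and THBS1 not. Interferon and inflammation genes kept it at 17 of 24, with NFKBIA kept and HAMP not. Bile acid and xenobiotic genes kept BRG1 at 8 of 13 (percentile 57.3), other liver cell types at 4 of 6 and neuronal and muscle genes at 2 of 11. Over the 3 comparisons, 6 of 42 percentiles lay below the lower limit and 0 above the upper. These values are not independent, since lists share genes and 2 of the comparisons share a control list.

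The 2 knockdowns left partly different BRG1 sites. Both kept 5436 control BRG1 peaks, BRG1 knockdown alone kept 6194, BRM knockdown alone 1203, and 31341 were kept by neither. These counts depend on list length, as the lists hold 18997 and 9968 peaks: among strong enhancers kept by a single knockdown, BRM knockdown kept 642 of 1639, and 892 of 1218 with equally long knockdown lists. If the knockdowns had acted independently within width deciles, 4035 would have been kept by both; both shares refer to the same control list. Comparing the same genes after both knockdowns, a comparison chosen after the lists were seen, secreted hepatocyte protein genes stood apart from the other 13 lists. They kept BRG1 in 48.3% after BRM knockdown and in 31.0% after BRG1 knockdown, a difference of 17.2 points, while matched random lists had a median of -20.7 (95% range -37.9 to -6.81; percentile 100). BRG1 was kept after BRM knockdown only at A1BG, AFP, AGT, AHSG, ALB, CP, F5 and ITIH2, which include albumin, alpha-fetoprotein, angiotensinogen, fetuin-A, ceruloplasmin and coagulation factor V. It was kept after BRG1 knockdown only at C3, CFB and F2, at 6 genes after both and at 12 after neither. Which genes fell in each group changed with the setting. With the authors' TSS names AHSG was kept after BRG1 knockdown only, and AMBP and FETUB after BRM knockdown only. With peaks within 10000 bp only, A1BG left the group kept after BRM knockdown only. With the widest 50% of each list that group was A1BG, AGT, ALB and SERPINA1. In the other direction, 10 SWI/SNF subunit genes kept BRG1 after BRG1 knockdown only and 0 after BRM knockdown only, and 8 immediate early genes did so, among them ATF3 and KLF4, and again 0 after BRM knockdown only. The differences of these 2 lists lay within the random range (percentiles 9.49 and 25.0). In the widest 50% of each list, 3 further lists passed the upper limit: liver transcription factors (97.525), TGF-beta, mesenchymal and matrix genes (98.9) and ribosomal protein genes (98.8).

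**Figure D4:**
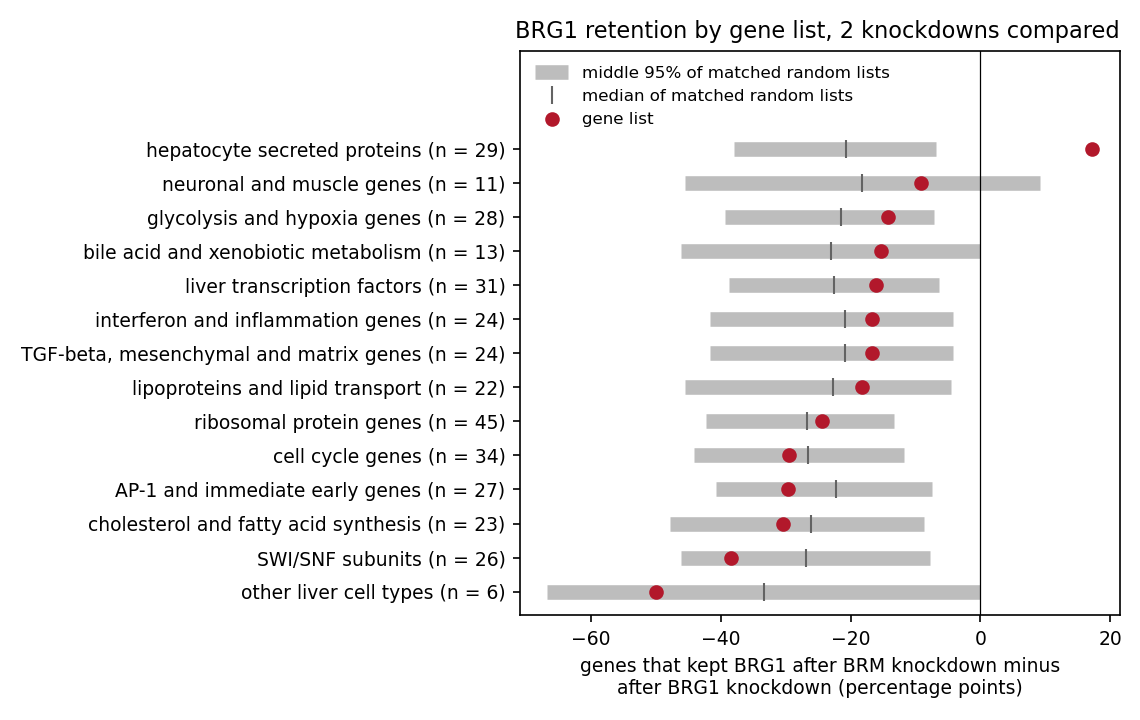
Red points give, for each gene list with its number of BRG1 genes, the share that kept BRG1 after BRM knockdown minus the share after BRG1 knockdown (percentage points); grey bars and ticks give the middle 95% and the median of matched random lists. Secreted hepatocyte protein genes lie at 17.2 points, outside their grey bar, and the other 13 lists lie within theirs.

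The albumin locus was chosen after its values were seen. ALB had 9 BRG1 peaks in control cells, of which the widest spanned 1184 bp (chromosome 4, 74270967 to 74272150), 0 after BRG1 knockdown and 5 after BRM knockdown. Only 1 of the 9 control peaks was kept after BRM knockdown, since 3 of the 5 peaks lay in the 1184 bp peak and 2 overlapped no control peak. AFP, the fetal counterpart of albumin next to it, had 5, 0 and 3 peaks, and 2 of its 5 control peaks were kept after BRM knockdown. No BRM peak was called at either gene in any of the 3 BRM lists.

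**Figure D5:**
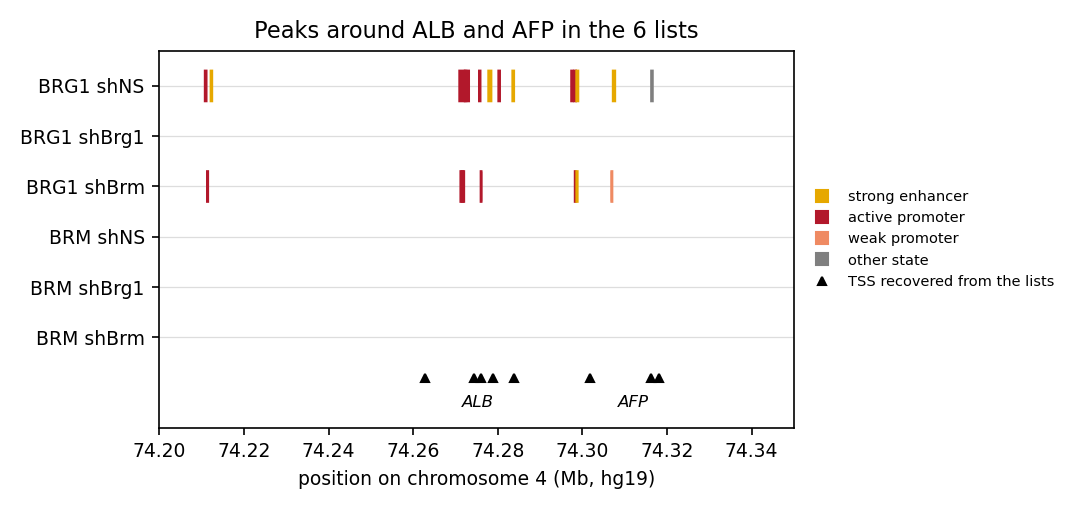
Peaks of the 6 lists around ALB and AFP on chromosome 4 (position in Mb, hg19), coloured by chromatin state and drawn with a thin outline so that narrow peaks stay visible; triangles mark TSS positions recovered from the lists. BRG1 peaks are present in control cells and after BRM knockdown, and no peak is listed after BRG1 knockdown or for BRM.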

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

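The tests of list length for the hepatocyte genes, of the library batch, of the input libraries, of a shorter list of the same sites and of chance overlap were chosen only after the result was seen, as were the ratios of odds ratios and the comparisons of strong enhancer with active promoter states and of the same genes after both knockdowns.

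The odds ratios of 4 pairs of comparisons differed, each pair tested by resampling chromosomes. The preference for promoters, by TSS distance, was smaller for BRM after BRG1 knockdown than for BRG1 after BRG1 knockdown (ratio of odds ratios 0.747; 0.590 to 0.920), and smaller for BRG1 after BRM knockdown than after BRG1 knockdown (0.616; 0.551 to 0.689). The preference for sites shared by both ATPases was likewise smaller for BRM after BRG1 knockdown (0.532; 0.352 to 0.861) and for BRG1 after BRM knockdown (0.670; 0.599 to 0.764), each against BRG1 after BRG1 knockdown. With the authors' promoter class the first ratio was 0.848 (0.663 to 1.06), and with a gap of up to 500 bp the third was 0.853 (0.477 to 2.02), so these 2 differences depend on the setting. Both also compare unlike control lists: 16587 BRM peaks, 80.7% within 1000 bp of a TSS, and 44174 BRG1 peaks, 47.0%. Each list had its own width deciles, so list composition and calling cannot be told apart from the antibody. The third ratio rests on 169 unshared BRM peaks.

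The genes of secreted hepatocyte proteins differed between the knockdowns: 17.2 percentage points more of them kept BRG1 after BRM than after BRG1 knockdown, where matched lists ran from -37.9 to -6.81. The shorter list after BRM knockdown would by itself give a difference below 0, as in the matched lists. This uses the same difference by which the gene list was picked, so it is not a separate test of list length. Matching the random lists also on the chromatin state of the widest peak left the list at percentile 99.99. The median of the matched lists moved from -20.7 to -13.8 points, and their range became -31.0 to 3.45. Matching on any strong enhancer peak instead gave percentile 99.995 (-34.5 to 0). These values argue against chromatin state as the whole cause. A part played by state stays open, because these matchings also used coarser width strata (5 in place of 10). Leaving out each chromosome in turn gave a lowest percentile of 100, against a single chromosome as the cause. The batch stays open, because all BRM knockdown libraries belong to the later part of the series, they have no input library of their own, and neither can be told apart from the knockdown. An effect of the loss of either ATPase also stays open and was not tested.

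BRG1 sites kept after BRM knockdown were fewer than after BRG1 knockdown, and among sites kept by a single knockdown, strong enhancers were kept by BRM knockdown in 39.2% and active promoters in 12.7% (odds ratio 3.53; 3.02 to 4.19; above 1 on 23 of 23 chromosomes), while weak promoters (77 by BRM and 1506 by BRG1 knockdown alone) and weak enhancers (21 of 2678 kept after BRM and 106 after BRG1 knockdown) were not part of this test. Taking the 9968 widest peaks of the BRG1 knockdown list, which cover 3071 kb against 1986 kb, gave 16.8% kept (16.5 to 17.2) against 15% (14.7 to 15.4). The whole BRG1 knockdown list had kept 26.3%, so a small gap remained at equal length. Since 96.5% of peaks of either knockdown list lay at control BRG1 peaks, this test cannot separate list length from the knockdown. With equally long lists the odds ratio was 3.48. Equal length was reached by dropping the narrowest BRG1 knockdown peaks, which left a minimum of 137 bp against 76 bp after BRM knockdown. The dropped peaks were thus picked by width, so this setting cannot decide whether a shorter list of the same sites was the cause. The shares kept by BRM knockdown rose to 73.2% in strong enhancers and 38.5% in active promoters, so the shares themselves depend on list length. Of the 4 BRG1 libraries after BRM knockdown, 0 lie outside the later part of the series, and 0 of the 8 input libraries came from BRM knockdown cells, so a batch, the lack of input and an effect of BRM loss cannot be told apart. The extent to which each hairpin lowered its target also stays open.

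BRM peaks called only after BRG1 knockdown lay at BRG1 sites in 93.4%. In the widest width decile of the list 2.06% of peaks were new (1.32 to 3.04), against 48.8% in the narrowest, so peaks close to the calling threshold could account for most of them. Overlap after shifting reached at most 2.11%. The shifts do not keep peaks at promoters, so the overlap to be had among promoter sites in general was not tested. A gain of BRM where BRG1 was lost would need fewer kept BRG1 peaks at gaining sites. This was tested only in the 34636 BRG1 sites without control BRM, which held 1335 of the 3168 new peaks. Of the 1203 such sites that gained BRM, 67.7% kept BRG1, against 9.89% of 33433 others (odds ratio 9.03, 8.08 to 10.0). Both calls come from the same knockdown cells and may both favour easily detected sites. A kept site needs only 1 bp of overlap and may have lost BRG1. The test therefore cannot decide whether BRM replaced BRG1, which stays open. A gain of BRM at sites that keep BRG1 was not tested and stays open.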

How the results depend on the processing

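The 200 bp windows, the widest 50% of each list, the authors' promoter class and TSS names, genes with a recovered TSS only, and all alternatives for the comparison of strong enhancers with active promoters, the ratios of odds ratios, sites that gained BRM and the same genes after both knockdowns were chosen only after the data were seen. The 7 odds ratios kept their direction and their side of the threshold under all 55 alternatives run, including that of strong enhancers (2.49 to 4.42), and so did the odds ratio of kept BRG1 at sites that gained BRM under 7 (7.57 to 19.1). Of 48 alternatives for the 6 ratios of odds ratios, 38 kept their side. Promoter ratios for BRM after BRG1 knockdown passed over BRG1 after BRM knockdown with a 500 bp gap (1.40) and the authors' promoter class (1.53) and turned without strata (0.619), and over BRG1 after BRG1 knockdown ended with the authors' promoter class (0.848). Ratios for shared sites, BRM after BRG1 knockdown over BRG1 after BRM knockdown, passed with equally long lists (0.366), 200 bp windows (0.275), the widest 50% (0.687) and no strata (0.434) and turned with a 500 bp gap (1.33), where that over BRG1 after BRG1 knockdown ended (0.853). The planned threshold on -log10 q was not run, because the lists hold no q-value, and lists of equal length were not run for BRM after BRM knockdown, which holds 90 peaks. No paired analysis was possible because a single list was deposited for all libraries of each group, and no library could be left out for the same reason. Depth is unknown and could not be varied. The cause of the changes below was not tested, except that a wider gap can only raise a kept share.

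Of 53 alternatives for the 9 shares, 40 moved beyond the counting interval, and several crossed 50%, such as 3 of those with 200 bp windows: new BRG1 peaks after BRM knockdown (3.46% to 52.6%), BRM shared with BRG1 (99.0% to 47.9%) and new BRM at BRG1 sites (93.4% to 44.6%). With a gap of up to 500 bp, the shares were 34.5% (BRG1 kept after BRG1 knockdown), 0.826% (BRM kept after BRM knockdown), 99.4% (BRM shared with BRG1), 27.9% (BRG1 shared with BRM), 68.5% (BRM kept after BRG1 knockdown), 19.9% (BRG1 kept after BRM knockdown), 13.2% (BRM new after BRG1 knockdown), 1.81% (BRG1 new after BRM knockdown) and 89.8% (new BRM at BRG1 sites). With equally long lists, the shares were 52.4% (BRG1 kept after BRG1 knockdown), 91.8% (BRM shared with BRG1), 50.8% (BRG1 shared with BRM), 57.7% (BRM kept after BRG1 knockdown), 46.4% (BRG1 kept after BRM knockdown), 36.2% (BRM new after BRG1 knockdown), 24.8% (BRG1 new after BRM knockdown) and 71.6% (new BRM at BRG1 sites). Without chromosomes 2, 14, 16, 17 and 20, the shares were 25.4% (BRG1 kept after BRG1 knockdown), 47.1% (BRM kept after BRG1 knockdown), 13.8% (BRG1 kept after BRM knockdown) and 28.8% (BRM new after BRG1 knockdown). With 200 bp windows, the shares were 19.9% (BRG1 kept after BRG1 knockdown), 0.386% (BRM kept after BRM knockdown), 47.9% (BRM shared with BRG1), 16% (BRG1 shared with BRM), 10.2% (BRG1 kept after BRM knockdown), 30% (BRM new after BRG1 knockdown), 52.6% (BRG1 new after BRM knockdown) and 44.6% (new BRM at BRG1 sites). With the widest 50% of each list, the shares were 31.1% (BRG1 kept after BRG1 knockdown), 98.5% (BRM shared with BRG1), 26.5% (BRG1 shared with BRM), 16.6% (BRG1 kept after BRM knockdown), 28.4% (BRM new after BRG1 knockdown), 4.23% (BRG1 new after BRM knockdown) and 94.4% (new BRM at BRG1 sites). With an overlap of 50% of the shorter peak, the shares were 98.7% (BRM shared with BRG1), 43.3% (BRM kept after BRG1 knockdown), 34.4% (BRM new after BRG1 knockdown) and 3.97% (BRG1 new after BRM knockdown).

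Of 168 alternatives for the percentiles of 42 list comparisons, 156 kept their side of the limits, 8 fell inside and 4 passed. Those that fell inside were liver transcription factors for BRM after BRG1 knockdown (2.79 with a 500 bp gap, 2.79 with the widest 50%), hepatocyte proteins for BRM after BRG1 knockdown (39.3, widest 50%), lipoproteins for BRG1 after BRM knockdown (4.13 with a 500 bp gap, 6.74 with the authors' TSS names, 14.1 with the widest 50%) and ribosomal protein genes for BRG1 after BRG1 knockdown (6.25 with a 500 bp gap, 4.96 with the authors' names). Those that passed were interferon genes for BRM after BRG1 knockdown (98.8, authors' names) and for BRG1 after BRM knockdown (98.1, widest 50%), cell cycle genes for BRM (0.7, widest 50%) and SWI/SNF subunits for BRG1 after BRG1 knockdown (97.6, authors' names). For occupancy, 85 of 112 alternatives kept their call. The odds ratio no longer passed for BRG1 at lipoproteins (2.20, within 10000 bp), bile acid genes (0.607) and neuronal genes (0.522, both authors' names) and hepatocyte proteins (1.30, widest 50%), and for BRM at cholesterol genes (2.23, widest 50%). It passed for BRM at glycolysis genes (2.09 with the authors' names, 2.76 with the widest 50%) and TGF-beta genes (2.30, widest 50%). Among genes with a recovered TSS only, the odds ratio for BRG1 no longer passed at SWI/SNF subunits (2.08), lipoproteins (1.76), bile acid genes (0.345), liver transcription factors (5.04), immediate early genes (4.40), cell cycle genes (2.72), ribosomal protein genes (1.80) and neuronal genes (0.438). It changed direction and no longer passed at hepatocyte proteins (0.770), cholesterol genes (0.917), glycolysis genes (0.744) and other liver cell types (1.04), and changed direction without passing either time at TGF-beta genes (0.957). For BRM it no longer passed at SWI/SNF subunits (2.57), cholesterol genes (2.85) and liver transcription factors (2.59), and changed direction without passing either time at lipoproteins (0.980), interferon genes (0.898) and other liver cell types (1.80). Of 56 alternatives for the difference between the knockdowns, 53 kept their side, and with the widest 50% liver transcription factors (97.525), TGF-beta genes (98.9) and ribosomal protein genes (98.8) passed the upper limit.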

Other observations

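The 60 peaks called for both antibodies after BRG1 knockdown and in no control list were mostly outside promoter and enhancer states: 24 of them (40%) were in heterochromatin or low-signal states, 12 (20%) in repetitive and 10 in transcribed states. The widest BRM peak among them was distal, 723137 bp from the nearest recovered TSS. They were looked at after the data were seen, and no explanation was tested.

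BRG1 peaks near secreted hepatocyte protein genes lay in strong enhancer states in 51.1% of 133 peaks, against 23.1% over all protein-coding genes. Lipoprotein and lipid transport genes had 47.7% and bile acid and xenobiotic genes 61.2% in that state, while SWI/SNF subunits had 5.08% and cell cycle genes 11%. Of the 133 peaks, 18 were kept after BRM knockdown (13.5%) and 10 after BRG1 knockdown (7.52%). Over all protein-coding genes, 16.4% of peaks were kept after BRM knockdown and 29.2% after BRG1 knockdown. These shares were chosen after the data were seen and were not tested against each other.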
